A study of Mus musculus with 4 samples.

How the data were processed

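Total RNA from sorted mouse T cells was measured on Illumina bead arrays, 2 from mice lacking MEKK2 and MEKK3 (dKO) and 2 from wild type (WT) mice. Per the labels' protocols, CD4+CD62L-CD44+ cells were sorted from spleen and lymph nodes, RNA was extracted with TRIZOL and cleaned on a column, and biotinylated cRNA was prepared with an Ambion kit. The groups and the replicate numbers 1 and 2 were taken from the sample titles. Nothing in the labels says whether the 2 arrays of a group came from separate animals. The p-values of single genes therefore measure the spread between these arrays, which may be partly technical.

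The deposited values are probe intensities on a linear scale, already background-subtracted, as the values below 0 show. How the authors made them is not given in the sources used here. From the values, the dKO and WT arrays of 1 replicate number shared 1 distribution, with sorted values within 0.0846 for number 1 and 0.0793 for number 2, while arrays of different numbers differed by up to 6979. The 2 arrays of a replicate number, 1 of each group, had therefore been normalized together. The labels do not say that the number marks any other batch. Mean deposited intensity was 86.9 on both arrays of number 1 and 119 on both arrays of number 2. A second table of non-normalized signals was not used, because its 8 columns (4 of signal and 4 of detection p) carry names that match no sample's labels.

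The design had been fixed before the data were examined, for raw signals with a detection p, and its rule for a table without detection p was followed instead. Intensities were floored at 16, taken to log2 and quantile normalized over the 4 arrays. The filter kept probes above the 40th percentile of mean log2 value, which lay at the floor, so that a kept probe exceeded the floor on at least 1 array. Of 45281 probes, 14673 were kept, and 30608 were at the floor on all 4 arrays. GEO's platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. Entrez IDs matched 34807 of the single-gene probes to the RefSeq table of GRCm38.p6, with 0 symbols changed, and that table was used for names and for which genes neighbour each other. Each gene was represented by its kept probe of highest mean, which left 8285 genes and 2128 unnamed probes. Of 39 named genes with more than 1 kept probe, 8 had probes of opposite sign (Camk4, Cd200, Furin, Klf4, Map2k5, Map2k6, Map3k1 and Taok3). Near-identical families such as the globins, the kallikreins and the Klra receptors may share probe signal and are uncertain as single genes.

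Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all 10413 features and a threshold of 0.05. The main fit had genotype alone and 2 residual degrees of freedom. The fit with the replicate number as a block, planned as an alternative, had 1. It is printed beside the main fit because the arrays of a replicate number had been normalized together. The labels do not say that the numbers pair the arrays, and there were 2 numbers. Gene lists, 28 in all, were tested with limma's camera at a preset correlation of 0.01 where at least 4 members were kept (25 lists). They were tested again with an estimated correlation and with fry. At the preset correlation camera compares a list's members with all other genes, so its p-values rest mainly on the scatter between genes. The permutation p-values given at the end were made by shuffling genes. A gene at the floor on both arrays of a group has a bound, written as "at least" N-fold, computed against the floor.

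The genes to name were Map3k2 and Map3k3, then in each direction the 12 genes of largest change past the threshold, completed up to 12 by unadjusted p among genes at least 1.5-fold apart with no overlap between groups, and up to 4 members of each list by unadjusted p. Any member of the TGF-beta, regulatory T cell, Th17, Th1, Th2 and sex-linked lists may be named. Other genes are said to have been chosen after their values were seen.

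The fits were tested on simulated arrays drawn from the real means and replicate-number difference, with 200 of 10413 features changed, 10 times. Features of like mean intensity were given a common SD estimated from the real arrays. The changed features were drawn only from those with a mean well above the floor. Without the block, 0.20% of 2-fold, 27.6% of 4-fold, 69.4% of 8-fold and 88.4% of 16-fold changes were called. With it, the shares were 60.6%, 99.6%, 100% and 100%. In simulations without any change, 0 features were called by either fit, and among the unchanged features of the changed simulations 24 of 102130 were called with the block and 0 without it. Of 250 list tests on unchanged arrays, 1 was called, with the block and the preset correlation. Features were simulated as independent and of equal spread at like intensity, which real genes are not. The shares called therefore need not hold for the real arrays.

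Several fits were seen before the final one. A fit of single probes, quantile normalized before the floor, called 0 of 14667 without the block and 25 higher and 13 lower with it. A gene-level fit in that order was run next, and was replaced by the floor-first order because the fixed design states it. It is kept among 24 alternative settings, of which 14 were planned and 10 were chosen after seeing the data. The planned filter on detection p was replaced by a filter above the floor on all 4 arrays, and no block for slides could be made. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

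For the closing section, 11 predictions were written down, and 8 of them have a test value. The value given for sex decides nothing, as each group held arrays of 1 sex. For the lower CD8 and NK cell list only plain values are given. The number of arrays limits the precision of every value.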

Results

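Expression was measured in CD4+CD62L-CD44+ T cells, the effector memory phenotype, from 2 dKO and 2 WT arrays. MEKK2 and MEKK3, encoded by Map3k2 and Map3k3, are kinases at the head of MAP kinase cascades. In the dKO mice MEKK2 was absent in all cells and MEKK3 was deleted in T cells by Cre under the Lck promoter, on the C57BL/6 background, per the labels. The study's title names TGF-beta-mediated helper T cell differentiation as its question. Between 12763 and 13218 probes of each array exceeded the intensity floor of 16, and 70.8% to 71.8% lay below it.

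The targeted Map3k3 had 1 kept probe, with a deposited intensity of 204 on dKO 1 and 246 on dKO 2 against 311 on WT 1 and 387 on WT 2. The dKO over WT ratio was 0.656 in replicate number 1 and 0.636 in number 2. The log2 difference was −0.63 (dKO mean 7.81 ± 0.06 and WT mean 8.44 ± 0.07, SD, n = 2 each), which did not pass in limma (adjusted p = 0.9997, and 0.291 with the replicate block). Both Map3k2 probes lay below the floor on all 4 arrays and check nothing. Where the Map3k3 probe lies relative to the deleted part is not known here, so its value does not check the labels either.

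Comparing dKO with WT cells, no gene passed the threshold in the main fit. Among the large differences without overlap between the groups were higher values in dKO cells of the globin genes Hbb-bs and Hbb-bt, of the sialyltransferase St6galnac2 and of the LIM protein gene Pdlim4. Lower values in dKO cells were seen for the chemokine Xcl1, the guanylate-binding protein Gbp2b and the gamma chain segment Trgv4 of the gamma delta T cell receptor. Limma called 0 genes higher and 0 lower of 10413 features, with a smallest adjusted p of 0.149. At an unadjusted p under 0.05 there were 182 higher and 175 lower, 357 in all, against 521 given by chance. The 2 groups did not overlap for 26.2% of features. Chance gives 33.3% for independent arrays without ties, which these were not, since many values were tied at the floor and arrays of 1 number deviated together.

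At least 2-fold apart with no overlap were 97 features higher in dKO and 68 lower. St6galnac2 was at 9.63 ± 0.44 in dKO and 5.17 ± 0.27 in WT (log2 intensity, SD, n = 2 each), a difference of 4.46. Its other kept probe differed by 0.63, so the size of this change depends on the probe. Hbb-bs differed by 4.54, Hbb-bt by 4.32, Ltb4r1, a receptor for leukotriene B4, by 2.54 and Pdlim4 by 2.39. Nrn1 differed by 1.61, Cysltr1, a receptor for cysteinyl leukotrienes, by 1.22 and Hebp1 by 0.95. St6galnac1, Clec4n and Tshz3 were at the floor on both WT arrays and at least 2.57-fold, 2.60-fold and 2.15-fold higher in dKO. None of them passed in limma's main fit, with adjusted p values from 0.195 to 0.937. With the replicate block St6galnac2, Hbb-bs, Hbb-bt and Pdlim4 passed, as given below.

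In the other direction, Xcl1 was at 5.88 ± 0.16 in dKO and 8.48 ± 0.24 in WT (SD, n = 2 each), a difference of −2.60. Trgv4 differed by −2.90, Cd160, a receptor of cytotoxic lymphocytes, by −1.70, Gpnmb by −1.65 and Camk4 by −1.36, although the kept probes of Camk4 had opposite signs. Gbp2b was at the floor on both dKO arrays and at least 4.01-fold lower. The NK cell receptor genes Klra3, Klrb1c and Klra16 were likewise at least 2.61-fold, 2.22-fold and 1.99-fold lower, and Plpp1 and Igf2 at least 2.11-fold and 2.02-fold. None of these passed in limma's main fit, with adjusted p values from 0.570 to 0.937. With the replicate block Xcl1 passed, as given below.

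The sex-linked transcripts separated the groups. Xist, which is expressed from the inactive X chromosome, was at 8.70 ± 0.20 in WT (SD, n = 2) and at the floor on both dKO arrays, at least 26.1-fold lower. The Y-linked Eif2s3y was at 8.21 ± 0.21 in dKO (SD, n = 2) and Kdm5d at 5.37 ± 0.55, and both were at the floor on both WT arrays. The WT arrays thus carried female and the dKO arrays male transcripts, and sex cannot be told apart from genotype in any comparison made here.

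With the replicate number as a block, limma called 10 features higher and 5 lower, 7 and 3 of them named genes, and 1198 passed at an unadjusted p under 0.05. Higher in dKO were St6galnac2 (adjusted p = 0.00459), Hba-a1, with a log2 difference of 4.37 (0.00741), Eif2s3y (0.00776), Hbb-bt (0.0141), Pdlim4 and Hbb-bs (0.0176 each) and the galectin gene Lgals3, with a difference of 1.65 (0.0281). Lower were Xist (0.00592), Xcl1 (0.0170) and Aqp9, a channel for water and glycerol, with a difference of −2.73 (0.0276). Aqp9 falls outside the rule for named genes and was chosen after its value was seen. Those calls rest on 1 residual degree of freedom and 2 within-number differences each. In replicate numbers 1 and 2, St6galnac2 differed by 4.34 and 4.58, Xcl1 by −2.55 and −2.66 and Lgals3 by 1.55 and 1.74. The St6galnac2 call rests on 1 of its 2 kept probes, and the other differed by 0.63 over both numbers.

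**Figure D1:**
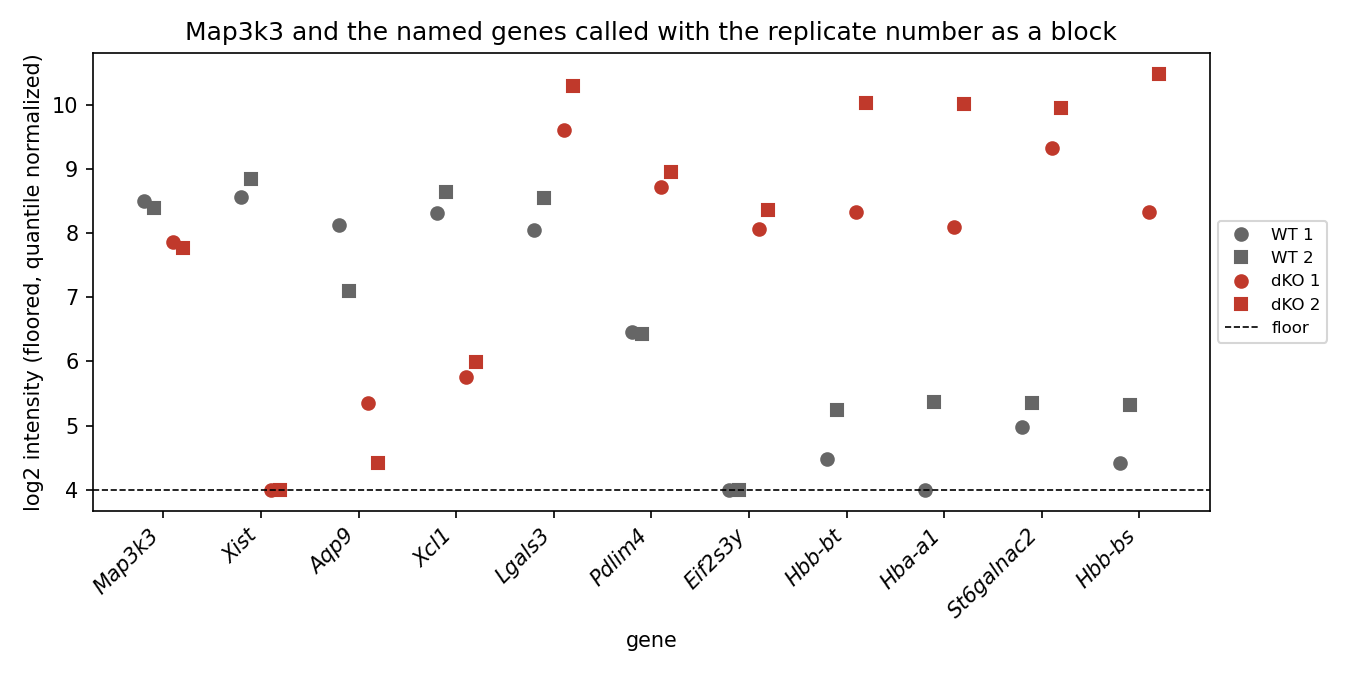
Log2 intensity (vertical axis) of Map3k3 and of the 10 named genes called with the replicate block, on each of the 4 arrays, with circles for replicate number 1, squares for number 2 and a dashed line at the floor. The dKO arrays (red) and the WT arrays (grey) do not overlap for any of the 11 genes, and Xist lies at the floor on both dKO arrays and Eif2s3y on both WT arrays.

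The gene lists, fixed before the data were examined, ask which programmes of the cells shifted together. As sets, genes of Th17 cells, which make interleukin 17, shifted higher in dKO, as did markers of myeloid and dendritic cells. Most members of both lists overlapped between the groups (8 of 15 and 13 of 19). Genes of the type I interferon response and markers of CD8 T cells and NK cells shifted lower. Genes of Th1 cells and of naive and central memory T cells did so as well. Limma's camera called these 2 lists higher and 4 lower of 25 at the preset correlation. With an estimated correlation it called 0, and fry called 0. Without a block, the split of the same arrays that crosses genotype and number called 4 lists, the myeloid and interferon lists among them. The split by replicate number, which follows the shared normalization, called 5, the myeloid list among them.

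Of 15 Th17 genes tested, 6 were higher in dKO with no overlap and 1 lower, with a median log2 difference of 0.36 (0.50 in replicate number 1 and 0.18 in number 2). Limma's camera gave an adjusted p of 0.00109 for the list, 0.000977 with the replicate block, and adjusted p = 0.748 with an estimated correlation. Ltb4r1 differed by 2.54, Il17re, a subunit of the interleukin 17C receptor, by 1.56, Tmem176b by 1.18, Ccr6, the homing receptor of Th17 cells, by 1.01 and Rora, a transcription factor of the lineage, by 0.52. The cytokine genes Il17a and Il17f were near the floor, with Il17a at the floor on both WT arrays and Il17f at a difference of 0.13, and Il21, above it on all arrays, differed by 0.38. Il12rb1 differed by −0.76. No member passed over all genes, and 2 did adjusted over the list alone (5 with the replicate block, all higher). The call ended without dKO 1 (adjusted p = 0.262 by limma's camera). Leaving out an array leaves 1 in its group, which is then assumed to vary like those of the other group, here and for the lists below.

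Of 14 Th1 genes, 6 were lower with no overlap and 1 higher, with a median of −0.36 (−0.56 in replicate number 1 and −0.16 in number 2). Tbx21, the master transcription factor of the lineage, differed by −0.83, Ifng by −0.99, Fasl by −0.89 and Il18r1 by 0.60. Limma's camera gave an adjusted p of 0.0264, 0.0834 with the replicate block, and adjusted p = 0.813 with an estimated correlation. Without dKO 1, WT 1 or WT 2 it was 0.531, 0.276 and 0.194 by limma's camera. No member passed, over all genes or adjusted over the list alone (0 of 14). With the replicate block 6 lower and 3 higher members passed adjusted over the list alone, the higher ones being Il18r1 and the chemokine genes Ccl3 and Ccl4, at differences of 1.11 and 0.82.

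Of 21 interferon response genes, 10 were lower with no overlap and 0 higher, with a median of −0.52 (−0.82 in replicate number 1 and −0.33 in number 2). Isg15 differed by −1.58, Ifit3 by −1.17, Mx2 by −1.01 and Ifi35 by −0.96. Limma's camera gave an adjusted p of 6.01e-08, 5.76e-07 with the replicate block, and adjusted p = 0.813 with an estimated correlation. No member passed, over all genes or adjusted over the list alone (0 of 21), and 4 lower ones did with the replicate block.

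Of 10 CD8 T cell and NK cell markers tested, 7 were lower with no overlap and 0 higher, with a median of −1.13 (−1.32 in replicate number 1 and −0.48 in number 2). Klrd1 and Ctsw differed by −1.19 and −1.12, while Cd8b1 differed by −0.16. Klre1 was at the floor on both dKO arrays and at least 3.34-fold lower. Limma's camera gave an adjusted p of 6.01e-08, 1.57e-06 with the replicate block, and adjusted p = 0.748 with an estimated correlation. No member passed over all genes, and 3 did adjusted over the list alone (7 with the replicate block, all lower).

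Of 11 naive and central memory genes, 3 were lower with no overlap and 0 higher, with a median of −0.19 (−0.01 in replicate number 1 and −0.38 in number 2), and Igfbp4, Foxp1 and the lymph node homing receptor Ccr7 differed by −1.20, −0.85 and −0.79. Limma's camera gave an adjusted p of 0.0352, 0.0306 with the replicate block, and adjusted p = 0.813 with an estimated correlation. Without dKO 2, WT 1 or WT 2 the adjusted p by limma's camera was 0.733, 0.429 and 0.119. Of 19 myeloid markers, 4 were higher with no overlap and 2 lower, with a median of 0.53. That median was 0.00 in replicate number 1 and 1.06 in number 2. The macrophage genes Adgre1, C1qc and Csf1r differed by 1.73, 1.31 and 1.00, and the dendritic cell gene Clec9a was at the floor on both dKO arrays. Limma's camera gave an adjusted p of 0.00182, 0.00342 with the replicate block, and adjusted p = 0.862 with an estimated correlation. Without dKO 2 the direction of the myeloid list turned (adjusted p = 0.797) and without WT 2 its adjusted p was 0.194 by limma's camera. No member of either list passed, over all genes or adjusted over the list alone (0 of 11 and 0 of 19). With the replicate block 2 lower naive genes passed adjusted over the list alone, as did 2 higher and 2 lower myeloid markers.

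Among the lists close to the study's question, the TGF-beta, regulatory T cell and Th2 lists were not called, unlike the Th17 and Th1 lists above. Of 10 TGF-beta response genes, 1 was higher and 2 lower with no overlap (median 0.32, adjusted p = 0.807 by limma's camera), with 1 member passing adjusted over the list alone, Tsc22d1, at the floor on both dKO arrays and at least 1.71-fold lower. Tgfbi had the largest difference of the list, 1.46 (1.17 in replicate number 1 and 1.76 in number 2), with overlap between the groups, and passed adjusted over the list alone with the replicate block. The ligands, receptors and SMADs had a median of 0.07 (adjusted p = 0.848 by limma's camera). Of 20 regulatory T cell genes, 1 was higher and 3 lower with no overlap (adjusted p = 0.807 by limma's camera). Foxp3 differed by 0.07, Gpr83 by −1.26, Izumo1r by −0.97 and Socs2 by 0.89, and Gpr83 and Izumo1r passed adjusted over the list alone with the replicate block. Tgfbr1 and Tgfbr2 differed by −0.13 and 0.10. The Th2 list had an adjusted p of 0.0567 by limma's camera, with Pparg, at the floor on both WT arrays, at least 4.91-fold higher, passing adjusted over the list alone with the replicate block, and Gata3 at a difference of 0.20. The remaining MAP kinase, cytokine, homing, activation, proliferation, apoptosis and stress lists were not called either. Median, mean and test differed in sign for 5 of the lists not called, those of follicular helper cells, of the T cell receptor complex, of MAP kinases, of other MAP3 kinases and of the ERK5 axis. Plasma cell, erythroid and sex-linked lists had fewer than 4 members tested.

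**Figure D2:**
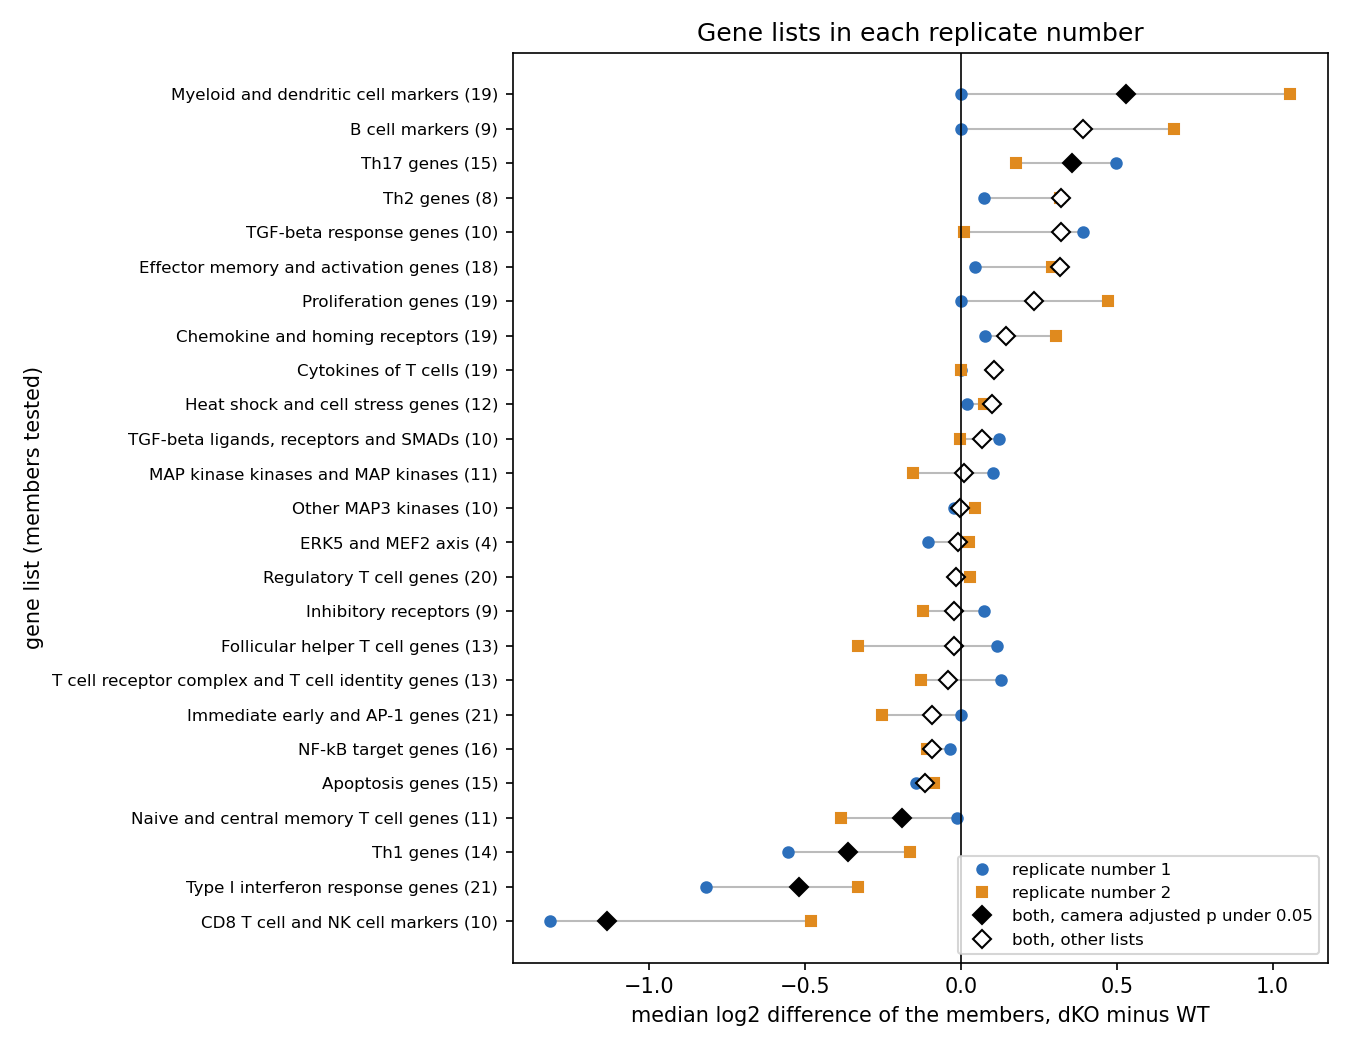
Median log2 difference (dKO minus WT, horizontal axis) of the members of each of the 25 tested lists, in replicate number 1 (circles), number 2 (squares) and both (diamonds, filled where limma's camera gave an adjusted p under 0.05 at the preset correlation). The CD8 and NK cell list lies lowest, at −1.32 and −0.48, and the myeloid list lies at 0.00 in number 1 and 1.06 in number 2.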

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

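Of 24 alternative settings, 10 were chosen after seeing the data. Without a replicate block, limma called 0 genes in either direction with medians equalized, the authors' values, the mean of probes, eBayes without trend, floors of 8 and 32, quantile normalization before the floor, probes above the floor on all 4 arrays, and any array left out (0 to 0). With log2(signal + 16) it called 3 higher and 1 lower, with robust eBayes 1 higher, and with no filter 57 higher and 39 lower, where most residual variances were exactly 0 and the fit is unreliable. The replicate block called 10 higher and 5 lower. With a block, it called 13 and 7 at floor 8, 12 and 6 at floor 32, 19 and 12 on the authors' values, 14 and 7 with quantile normalization before the floor, and 8 and 5 without trend. All 15 blocked calls were shared in the first 4 of these and 12 in the last. Arrays of the same number deviated together (correlation 0.472), as shared processing would give, and the labels name no pairing. The log2 difference of Map3k3 stayed between −0.68 and −0.58 in every alternative, with no call. Of 2465 single-gene values under alternatives, 22 had another sign.

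With no filter and at floor 8, a list with too few members for the main fit was also called higher, and it is not named below. Lists called higher numbered 8 with no filter, 4 with the mean of probes and 4 at floor 8. There were 0 higher and 0 lower with an estimated correlation, with fry and with both the block and an estimated correlation. With an array left out they numbered 1 to 3 higher and 2 to 5 lower. Adjusted p values by limma's camera with an estimated correlation were 0.748 (Th17, CD8 and NK), 0.813 (Th1, naive, interferon) and 0.862 (myeloid), and 0.868 for all 6 with the replicate block as well. By fry they were 0.555, 0.284, 0.785, 0.967, 0.416 and 0.971 (Th17, CD8 and NK, Th1, naive, interferon, myeloid). The Th1 call ended with the replicate block (0.0834), which ended no other list call, and the naive call with the mean of probes (0.110). With an array left out, adjusted p by limma's camera ran from 0.00358 to 0.262 (Th17), 0.00276 to 0.531 (Th1), 0.00494 to 0.733 (naive), 2.94e-09 to 0.797 (myeloid, reversed without dKO 2), 2.53e-07 to 0.00457 (interferon) and 2.51e-07 to 0.00269 (CD8 and NK). Lists not called in the main fit gained a call 14 times in the direction they had. By limma's camera the Th2 list did so with log2(signal + 16) (adjusted p = 0.00858) and on the authors' values (0.0287). It also did so with no filter (4.78e-05), the mean of probes (0.0489) and floor 8 (0.0139), and without dKO 1. The Th2 list was not called by limma's camera at floor 32 (adjusted p = 0.272). Nor was it with probes above the floor on all 4 arrays (0.978), which left 4 of its members. The effector memory list gained a call with no filter (0.00644) and the mean of probes (0.0428). The proliferation, homing and heat shock lists did so with no filter. Without dKO 1 the proliferation list did so too, as did the immediate early list without WT 1 and without dKO 2. The B cell list gained one in the other direction, lower without dKO 2, and its range was 0.00758 to 0.700 with an array left out. The cause was not tested in any of these cases. Of the probes, 70.8% to 71.8% lay below the floor, where no difference can be measured.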

Other observations

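The tests of the Th17 list, of the neighbours of the targeted genes and of red cell precursors were chosen only after results were seen, as 1 of the erythroid markers, Slc4a1, was already in a fixed list. The test on further macrophage markers was written before those were looked at. How far a value had to miss its bound, and that all window lengths had to give the same answer, was decided after the values were seen.

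A few genes known from splenic macrophages, picked after their values were seen, had higher values in dKO. Spic, a transcription factor of red pulp macrophages, differed by 1.68, the iron exporter Slc40a1 by 1.55, Fcgr4 by 2.43 and Vcam1 by 1.35. Each was higher on both dKO arrays than on both WT arrays, and none passed in limma.

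These macrophage genes, with the globins, may come from red pulp macrophages left in the dKO sort, although the CD4 gate would remove most of them. Of 18 further markers 11 were tested, and the prediction written beforehand, a median above 0 in both replicate numbers, was not met. The median was 0 in number 1 and 0.76 in number 2. Only 2 of the 11 were higher with no overlap. The outcome written beforehand against macrophages, a median at or below 0 in either number, was met without any margin. The question is left open by a rule set after the values were seen. That rule asks a median to miss 0 by more than the members' SD, 0.315 in number 1. Genes already seen to differ had also been left out of the markers, and 5 of the 11 never came 1 log2 unit above the floor. Red cell precursors were tested on 8 of 27 erythroid transcripts, predicted to differ by over 1. Their higher median was 0.0839 (SD 0.845) in number 2 and the other 0.02 (SD 0.353), below that prediction. This excludes nothing, because most of the 8 have a high baseline in both groups that would hide a small share and 2 never came 1 log2 unit above the floor. Of the fixed erythroid and platelet list, 11 genes were on the array and 2 were kept, Hba-a1 and Slc4a1. The rest lay at the floor on all 4 arrays, where no difference can be measured. Slc4a1, the transcript most specific to red cells, was at the floor on both WT arrays and on dKO 1 and 1.76 higher on dKO 2, so precursors stay open. Sex stays open as well.

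The higher Th17 list could come from the same macrophages. In replicate number 1 its median lay 0.50 above that of the myeloid list (one-sided permutation p = 0.00967). That test rests on 1 pair of arrays and was chosen after both medians had been seen. A second test left out Ltb4r1, Tmem176a and Tmem176b and found that the other 12 genes changed by −0.27 between numbers 1 and 2 where the macrophage markers changed by 0.71 (two-sided permutation p = 0.00103). All 3 of the genes left out were larger in number 2, so parting them from the rest shaped that outcome, and Rora, kept in, was larger there too (0.23 and 0.82). Genes are also not independent. Neither test excludes macrophages, which stay open. Sex, for which Xist differed by −4.70 or more in size, being at the floor on both dKO arrays, with no array of the other sex in either group, cannot be told apart from genotype.

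St6galnac2, Cygb, St6galnac1 and a gene model without a name, all higher in dKO, lie within 5 neighbouring tested genes, 79 to 83 tested genes away from Map3k3, and Cygb was chosen after its value was seen. DNA of another strain kept around the targeted gene might do this. Among 100 tested genes on each side of Map3k3, 8 were 2-fold apart, a number reached by 2.00% of other windows. That was the length written down. With up to 200 genes on each side, cut to 346 in all by the chromosome end, the share was 23.0%. With 50, too few to reach the 4 genes, it was 71.2%. As the windows were chosen after those genes were seen, the question stays open. Around Map3k2, in a window cut to 146 genes in the same way, 2 genes were 2-fold apart, which 51.0% of other windows reached. No excess was seen there.

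For the lower CD8 and NK cell list, 10 NK cell transcripts were looked at, chosen after results were seen. Some of the 10 belong to that list and had already failed the filter, being at the floor on all 4 arrays. Of the 10, 1, Klrb1c, exceeded the floor on both WT arrays, and their median was 4 on the log2 scale, the floor itself. The choice of transcripts helped to fix that median. The 10 do not include Klra3, Klra16 and Klre1, named above, which also exceeded the floor on both WT arrays. The values of the 10 therefore do not show that NK cell transcripts were absent from the WT arrays. Zbtb16, the transcription factor of invariant NKT cells for which a test had been written beforehand, was at the floor on all 4 arrays and gave no answer.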
